A study of Rattus norvegicus with 15 samples.

How the data were processed

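Gene expression was measured in testes of LBNF1 rats, an F1 hybrid laboratory strain, on Affymetrix 3' expression arrays, in which biotin-labelled cRNA made from total RNA is hybridised to probe sets of short oligonucleotides. Per the labels, the rats were 25 to 27 weeks old, RNA was extracted with silica columns, and 10 µg of total RNA went into each labelling. The series holds 10 control and 5 irradiated samples, grouped by their titles. The labels call them biological replicates and do not say whether each is a different rat, so the p-values measure the spread between these samples. The irradiation was 6 Gy to the lower abdomen, per the labels' protocols, which carry the same text for every sample. The source field places the control testes before irradiation. The time between irradiation and collection is not given in the sources used here.

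The deposited table holds 1 log2 value per probe set and array, for 31099 probe sets. The signals were made with MAS5, per the submitters' processing notes, with no version. How these signals were scaled, filtered or logged is not given in the sources used here. The log base was read from the values: the hybridisation spike-ins, at nominal concentrations of 1.5, 5, 25 and 100 pM, rose by 0.889 log2 units per doubling in the control arrays and 0.943 in the irradiated arrays. The zero point of the scale stays unknown, and between 71.5% and 79.6% of the values of an array lay below 0. The medians over non-control probe sets were -1.61, -1.45, -1.46, -1.47, -1.37, -1.49, -1.39, -1.51, -1.50 and -1.41 in control replicates 1 to 10 and -1.26, -1.34, -1.29, -1.38 and -1.28 in irradiated replicates 1 to 5. Genes were not centred, since levels within an array differed by up to 18.7 log2 units. No array column was left unused (0 columns), and no pair of arrays held identical values. The planned analysis had assumed linear signals and a pseudocount. The table was already on a log scale, so the values were used as deposited, and pseudocounts were tried only as alternatives on the back-transformed scale. Arrays carry no read depth, and their number limits the precision.

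Probe sets were named from the platform's annotation of 2016. Of all probe sets, 20832 had 1 gene symbol, 436 had several and 9831 had none in the table used, and only those with 1 symbol were given a gene. Gene identifiers of 20764 of these were found in a RefSeq gene table of the assembly GRCr8, used for names only, and no symbol changed through it. No genome positions are reported. The 57 AFFX control probe sets were kept for quality measures and left out of the tests.

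A probe set was tested if its value reached its array's median in at least 5 of the 15 arrays, a filter that ignores the groups. It kept 18711 probe sets and left out 12331. Irradiated and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided) with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, with a threshold of 0.05. For genes with several probe sets, the one with the highest mean over all 15 arrays stood for the gene, which gave 10841 genes. Among the 2692 genes with several tested probe sets, 456 had probe sets past the threshold in opposite directions. Errors of log2 changes are limma's moderated standard errors. All adjusted p-values of probe sets and genes come from this limma model.

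The table used here carries no detection calls. A probe set below its own array's median in every array of a group was treated as dim there, with only a bound on its level. For such a gene the text gives the brighter group over the dimmer one as "at least N-fold". That bound sets the mean of the brighter group against the mean, over the dim group's arrays, of the higher of the array median and the probe set's own value. Where only some arrays of a group lay below their medians but the group's mean did, the change was taken with every array at no less than its median and is given as "at least" for a rise and "at most" for a signed fall. Values below the median give no order, although the rule for named genes, fixed before the data were examined, ranked measured means that include them.

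Before the data were examined, 24 gene lists of testicular cell types, their possible contaminants and radiation-related processes were fixed from textbook knowledge. Members that were not on the array or did not pass the filter were not tested, and member counts below are of tested members. Tested were 12 of 32 fixed members for spermatocytes, 15 of 28 for round spermatids and 14 of 26 for inflammation and chemokines. The numbers were 8 of 20 for undifferentiated spermatogonia and for lymphocytes, 4 of 14 for differentiating spermatogonia, 4 of 13 for mast cells and 7 of 17 for complement. Each list's 3 or more tested members were compared with the other genes by limma's camera with a preset inter-gene correlation of 0.01, 2-sided, adjusted over the 24 lists. Camera with an estimated correlation and fry were alternatives. The named genes were fixed by a rule: the 5 genes with the highest and the 5 with the lowest log2 change among genes past the threshold whose irradiated arrays all lay on the same side of all control arrays, leaving out symbols that are only model names; of each list the 2 members with the largest absolute change past the threshold; and Prm1, Sycp3, Gfra1, Sox9, Insl3 and Cdkn1a whether or not they passed. Sox9 was not analysed here. Further genes named as list examples, and genes with large changes that reached the array median in both groups, were chosen after their values were seen.

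Quality measures per array were the median and the 75th and 90th percentiles, the difference between 3' and 5' probe sets of actin and Gapdh, the spike-in response and correlations between arrays. Their group means were compared by an exact 2-sided permutation test over all 3003 splits of 15 arrays into 10 and 5, whose smallest possible p is 0.000333. Per-array list scores were compared in the same way.

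The test was checked on simulated data for 18711 probe sets, with the real probe sets' control means and spreads and independent noise. Only a small part of the probe sets was changed, whereas 15598 passed in the real data. The rates below therefore do not carry over to the real comparison. For the simulated irradiated against control comparison it recovered 92.5% of probe sets changed by 2.00 log2 units, 80% of those changed by 1.00 and 25% of those changed by 0.50, with 6 false calls among 127. In a simulation with 1 of 24 lists shifted, only that list passed. Genes were simulated without correlation, so this does not measure false calls among lists whose genes move together.

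Alternatives were no filter and a stricter one, several pseudocounts, quantile normalization, centring of arrays on their median or on the Sertoli cell list, trended and robust eBayes, array weights, an exact Wilcoxon test, a replicate block, subsets of the controls, a stricter threshold, the mean of a gene's probe sets, other list tests and each array left out in turn. A pseudocount at the 10th percentile, the controls with the highest actin ratio left out and the actin ratio as a covariate were added after the data were seen. The alternatives keep the representative probe sets chosen for the comparison of all 15 arrays, which was decided after a first run in which subsets of arrays chose their own had been seen.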

Results

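The series compares testes of irradiated rats with control testes and asks how radiation changes gene expression in this organ. The testis holds germ cells at successive stages (spermatogonia, meiotic spermatocytes, round and elongating spermatids) inside tubules lined by Sertoli cells and wrapped in peritubular myoid cells, with Leydig cells, macrophages and vessels between them. Expression was measured on 15 arrays, 10 from control testes and 5 from testes of rats given 6 Gy to the lower abdomen. A change is given as irradiated minus control on the log2 scale.

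The 2 groups were far apart. Pearson correlations across probe sets lay between 0.918 and 0.96 among control arrays, between 0.958 and 0.972 among irradiated arrays, and between 0.219 and 0.277 between the groups. The first principal component held 87.5% of the variance and separated the groups, and the second held 2.1%. Control replicates 6, 7 and 8 stood apart on the second component and had the highest differences between the 3' and 5' actin probe sets, a measure of RNA integrity, at 1.89, 1.38 and 1.44 log2 units. The mean of this difference was 1.02 ± 0.42 in control arrays (SD, n = 10) and 1.02 ± 0.10 in irradiated arrays (SD, n = 5; exact permutation p = 0.967, adjusted p = 0.974 over 8 measures). The array level differed: the median was -1.47 ± 0.07 in control and -1.31 ± 0.05 in irradiated arrays (exact permutation p = 0.000666, adjusted p = 0.00133), and the 75th percentile was -0.24 ± 0.05 and 0.14 ± 0.06 (exact permutation p = 0.000333, the smallest possible; adjusted p = 0.000888). The spike-in response was steeper in irradiated arrays by 0.0537 log2 units per doubling (exact permutation p = 0.0117, adjusted p = 0.0187).

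**Figure D1:**
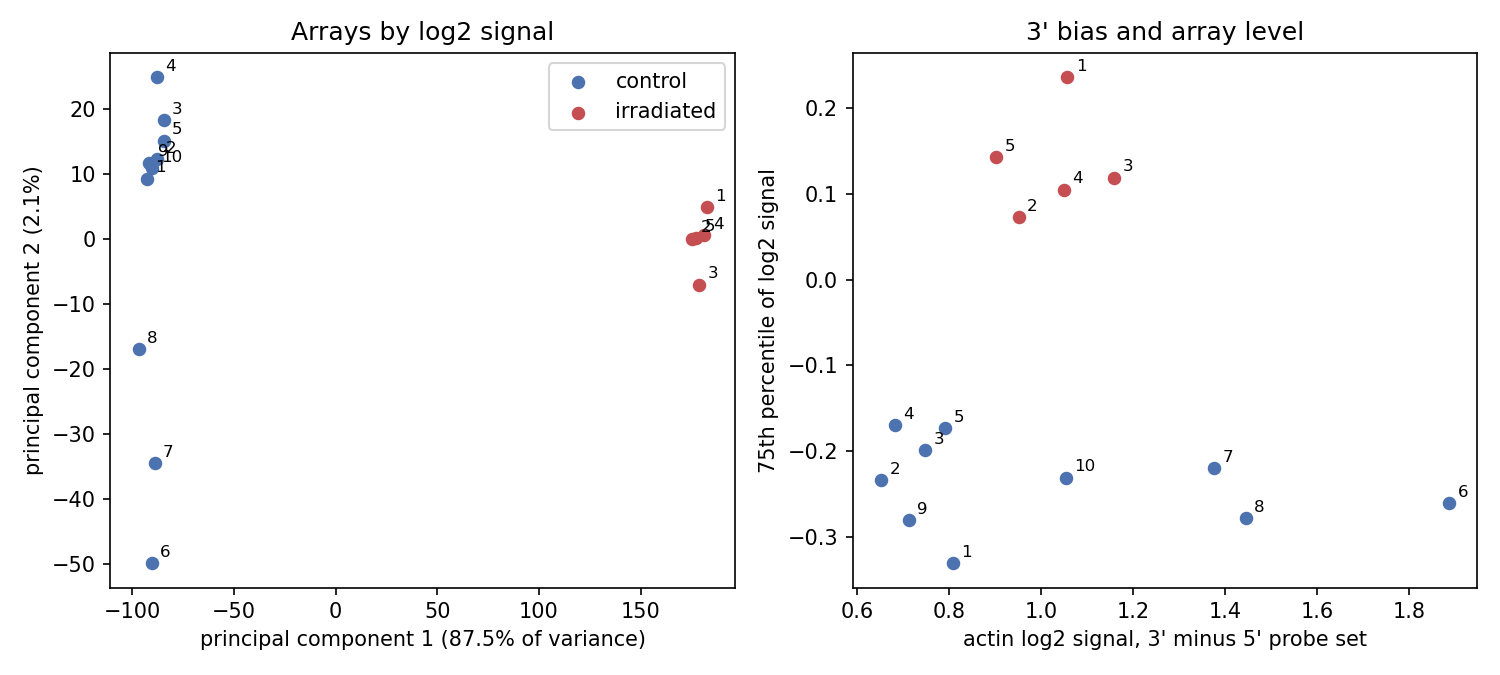
Each point is 1 array, numbered by replicate, blue for control and red for irradiated testes. Left, scores on the first 2 principal components of log2 signal, with 87.5% and 2.1% of the variance; right, the 75th percentile of log2 signal against the log2 difference between the 3' and 5' actin probe sets, where all 5 irradiated arrays lie above all 10 control arrays on the vertical axis and control replicates 6, 7 and 8 lie farthest right.

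Irradiated testes showed lower signals of genes of meiotic and later germ cells and higher signals of genes of Sertoli, Leydig and peritubular cells, macrophages and extracellular matrix. The Sertoli, peritubular and macrophage lists did not pass when camera estimated the correlation between genes (adjusted p = 0.165, 0.154 and 0.165). Of 10841 genes tested, 9272 (85.5%) passed an adjusted p of 0.05 (limma), 5161 higher and 4111 lower in irradiated testes. In measured means, those of dim genes included, changes of at least 2-fold were found in 3453 higher and 2474 lower genes, and changes of at least 8-fold in 480 higher and 811 lower genes. In 7539 genes (69.5%) the 5 irradiated arrays all lay on the same side of all 10 control arrays, where chance gives 0.0666%. Of the lower genes, 1311 lay below the array median in every irradiated array, and 597 of the higher genes did so in every control array. Among 18711 probe sets, 15598 passed, 9172 higher and 6426 lower. The median change of all genes tested was 0.20, which became -0.06 after quantile normalization, -0.13 after centring arrays on their median and -1.53 after centring them on the Sertoli cell list. With that last centring 14.2% of the changed genes were higher in irradiated testes, against 55.7% as deposited. List medians are therefore also given relative to all genes.

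The rule for named genes, which used measured means, picked 5 lower genes: Crisp2, which encodes a cysteine-rich sperm protein, Fabp9, a testis fatty acid binding protein, Tnp2, a transition protein of condensing spermatid chromatin, Fam229b, and Akap4, a scaffold of the sperm tail's fibrous sheath. All 5 were dim in every irradiated array. Crisp2 was at least 110-fold lower, Fabp9 at least 93.1-fold, Tnp2 at least 103-fold, Fam229b at least 114-fold and Akap4 at least 68.1-fold lower in irradiated testes. The 5 higher genes it picked were dim in every control array. Wnt4, a secreted signalling protein, was at least 17.3-fold higher, Testin, a product secreted by Sertoli cells, at least 21-fold, the matrix protein vitronectin (Vtn) at least 4.61-fold, the lipolysis inhibitor G0s2 at least 6.76-fold and the phospholipid transfer protein Pltp at least 10-fold higher. Since these picks rest on signals below the array median, neither their order nor whether other genes changed more was measured. Among genes above the array median in at least 1 array of each group, 10 with large changes were chosen after the values were seen. Ptn rose by 4.67 ± 0.23 (SE) and Serping1 by 4.55 ± 0.08, and Timp1, Cd36 and Serpinb9, whose control means lay below the array median, by at least 4.74, 4.43 and 4.43. Prm1, Smcp, Oaz3, Odf1 and Hspb9, whose irradiated means lay below it, had changes of at most -6.92, -6.91, -7.01, -6.86 and -6.54. Their order was not measured. All 10 had limma adjusted p-values of 2.33e-09 or smaller.

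Every tested member of the 3 lists of meiotic and later germ cells fell. The spermatocyte list, genes of meiosis, fell in 12 of 12 members with a median change of -4.46 (-4.66 relative to all genes; camera adjusted p = 8.63e-06, and adjusted p = 0.0266 with an estimated correlation). Sycp3 (probe set 1387614_at), a component of the synaptonemal complex that joins meiotic chromosomes, had a log2 signal of 4.18 ± 0.16 in control testes (SD, n = 10) and was at least 45-fold lower after irradiation (adjusted p = 1.21e-18). The germ cell lactate dehydrogenase Ldhc was at least 101-fold lower and the meiotic cyclin Ccna1 at least 12.4-fold lower. The round spermatid list fell in 15 of 15 members with a median of -5.64 (-5.84 relative to all genes; camera adjusted p = 1.30e-07, and adjusted p = 0.0137 with an estimated correlation), and Tssk2, a testis-specific kinase, was at least 45.7-fold lower and the axonemal gene Spag16 at least 9.29-fold lower. The elongating spermatid list fell in 24 of 24 members with a median of -7.39 (-7.59 relative to all genes; camera adjusted p = 4.24e-11, and adjusted p = 0.032 with an estimated correlation). Prm1 (1394007_at), which encodes protamine, the protein that packs sperm DNA, was 6.08 ± 0.26 in control (SD, n = 10) and -2.20 ± 2.24 in irradiated testes (SD, n = 5), where the mean lay below the array median, so that the change was at most -6.92 (adjusted p = 2.01e-09). With dim members set at their bounds, the medians of the 3 lists were -3.08, -4.17 and -5.95.

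Genes of spermatogonia, the dividing germ cells that include the stem cells, went both ways. Of 8 tested members of the undifferentiated spermatogonia list, 4 rose, 2 fell and 2 did not pass. The list did not pass with camera (median 0.45, 0.25 relative to all genes; adjusted p = 0.785), whereas its median in each array, relative to that of all genes, changed by -0.24 (exact permutation p = 0.03, adjusted p = 0.0327 over 24 lists). Gfra1 (1367954_at), the receptor through which Gdnf acts on spermatogonial stem cells, was at least 2.25-fold lower (adjusted p = 8.93e-08), while its other tested probe set did not pass (-0.27, adjusted p = 0.088). Bcl6b changed by at most -0.40 on the log2 scale. Id4 rose by 0.67, with its probe sets going from -0.84 to 0.84, while Etv5 (-0.25, adjusted p = 0.0829, another probe set 0.78, adjusted p = 0.02) and Uchl1 (0.23, adjusted p = 0.13) did not pass. The integrin gene Itga6 rose by 3.62 ± 0.17 (SE), but its probe sets went in both directions, from -0.55 to 3.62. Of 4 tested members of the differentiating spermatogonia list, the receptor gene Kit, which Leydig cells also express, was at least 3.45-fold higher, Ccnd2 rose by 1.13, Tex101 was at least 11.1-fold lower, and Rarg did not pass (0.26, adjusted p = 0.0577). This list did not pass with camera either (adjusted p = 0.797), whereas its median in each array relative to all genes rose by 0.42 (exact permutation p = 0.000666, adjusted p = 0.000761). Its median change of 0.69 and fry's direction were opposite in sign. With arrays centred on the Sertoli cell list, the medians of both lists turned to -1.28 and -1.03.

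**Figure D2:**
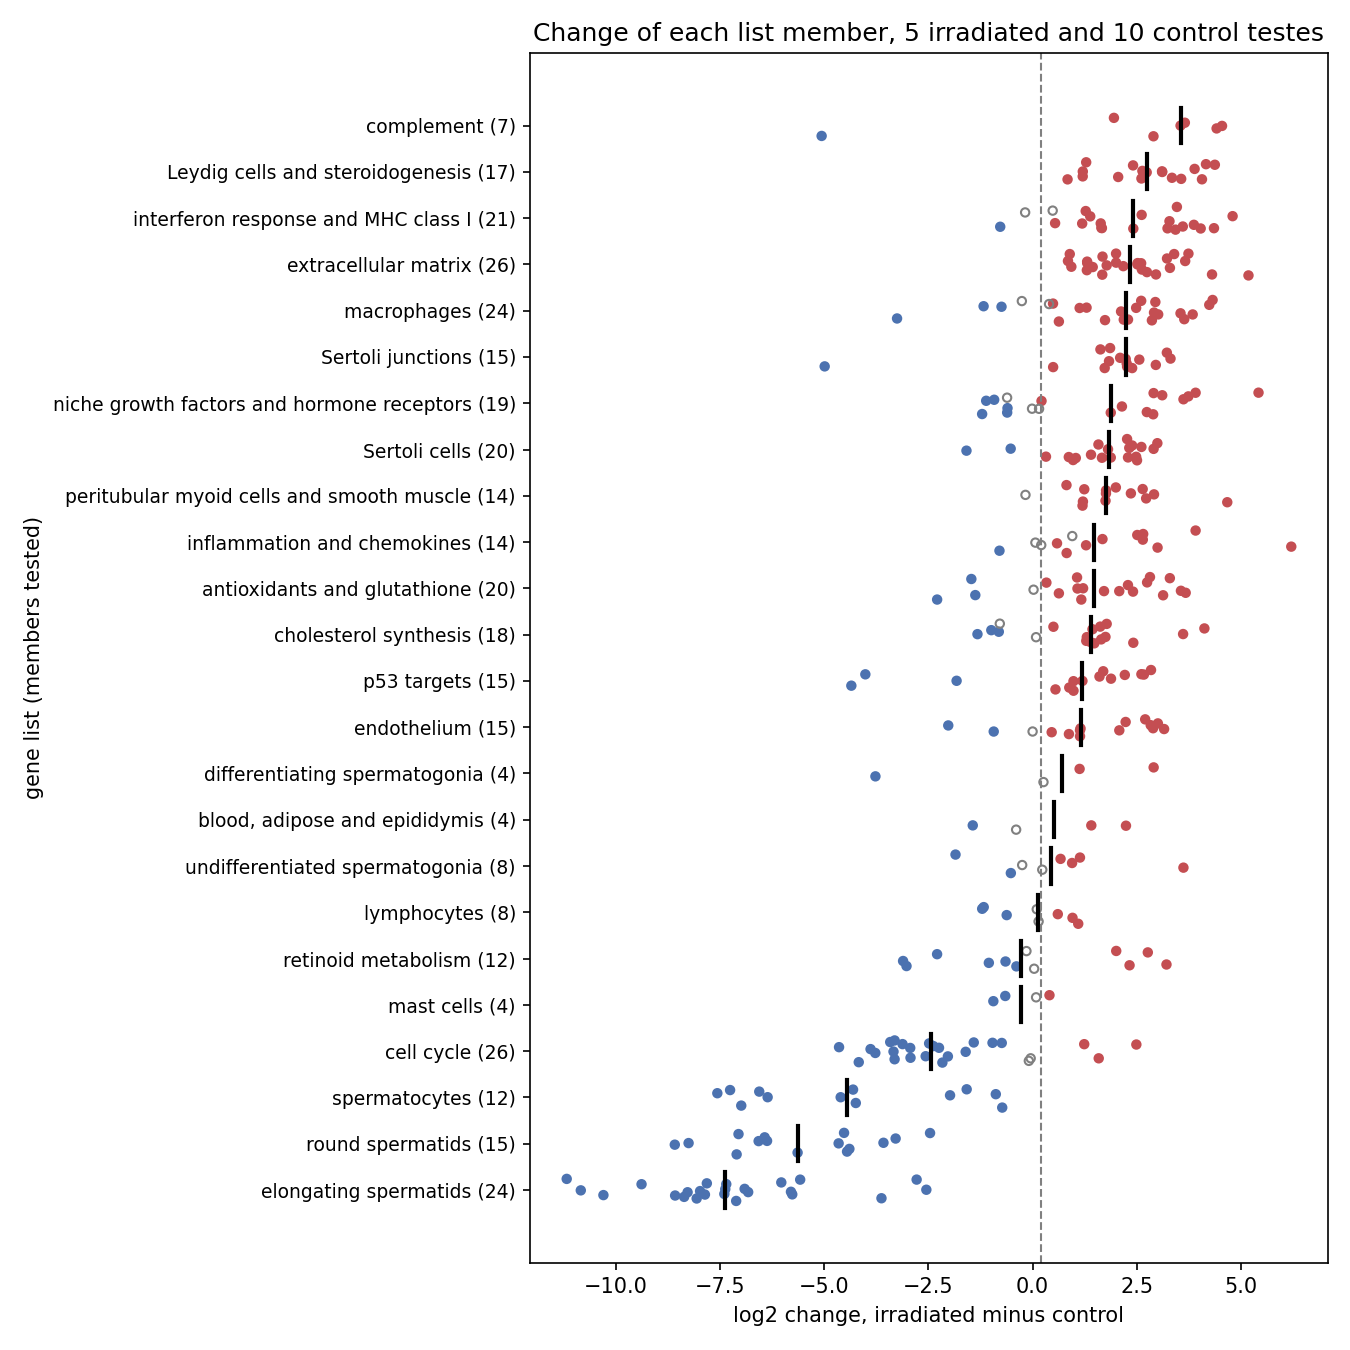
Each point is 1 tested gene of a list, placed by its log2 change, irradiated (n = 5) minus control (n = 10). Filled points passed an adjusted p of 0.05 (red higher, blue lower), open points did not, black bars are list medians and the dashed line is the median of all genes (0.20). The spermatocyte, round spermatid and elongating spermatid lists lie at medians of -4.46, -5.64 and -7.39 with no member above 0, and values of genes that were dim in a group are measured means, not bounds.

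Sertoli cell genes rose in 18 of 20 tested members and fell in 2, with a median of 1.84 (1.64 relative to all genes; camera adjusted p = 0.000394). With an estimated correlation the list did not pass (adjusted p = 0.165). The intermediate filament gene Vim rose from 1.61 ± 0.18 (SD, n = 10) to 4.61 ± 0.23 (SD, n = 5), a change of 2.99 ± 0.11 (SE, adjusted p = 1.86e-13). Kitlg, the ligand of the Kit receptor, rose by 2.90 ± 0.12 (0.83 in another probe set), and the transcription factor genes Gata4 and Wt1 rose by 2.61 and 2.32 (0.94 and 1.59 in another probe set of each). The inhibin subunit genes Inha and Inhbb rose by 1.04 and 0.97, less than the list median. Serpina5 fell by 1.59. Genes of Sertoli cell junctions rose in 14 of 15 members, among them Cldn11 and Gja1, which the Sertoli cell list also holds, with a median of 2.23 (2.03 relative to all genes; camera adjusted p = 0.00168). That call did not hold with an estimated correlation (adjusted p = 0.213). Cdh2, which encodes N-cadherin, rose by 3.31 ± 0.16. Nectin3, whose product spermatids carry at their contact with Sertoli cells, changed by at most -4.77, and its 3 probe sets had measured changes from -7.08 to -1.89.

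Leydig cell and steroidogenic genes rose in 17 of 17 members, with a median of 2.74 (2.54 relative to all genes; camera adjusted p = 2.86e-05, and adjusted p = 0.0463 with an estimated correlation). Insl3 (1388241_at), a peptide hormone of Leydig cells, rose from 0.50 ± 0.42 (SD, n = 10) to 4.06 ± 0.23 (SD, n = 5), a change of 3.57 ± 0.19 (SE, adjusted p = 2.39e-11). The prolactin receptor gene Prlr rose by 4.37 ± 0.10 (2.29 and 0.42 in its other probe sets) and the adhesion molecule gene Vcam1 by 4.16 ± 0.13. The steroidogenic enzymes Cyp17a1 and Hsd3b1 rose by 4.07 and 3.89, the luteinizing hormone receptor Lhcgr by 3.11, and Star, which carries cholesterol into mitochondria, by 2.74, while Hsd17b3 rose by 1.20. Cholesterol synthesis genes rose in 13 of 18 members and fell in 3, and the list did not pass (median 1.41, 1.21 relative to all genes; camera adjusted p = 0.0642). Its median turned to -0.32 with arrays centred on the Sertoli cell list. Msmo1 rose by 3.61 ± 0.10 and Tm7sf2 was at least 2.36-fold higher, whereas Fdps, Fdft1 and Sqle fell by 1.32, 0.99 and 0.81, although another probe set of Fdft1 did not pass (-0.14, adjusted p = 0.203).

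Peritubular myoid and smooth muscle genes rose in 13 of 14 members, with a median of 1.76 (1.56 relative to all genes; camera adjusted p = 0.00115). This list did not pass with an estimated correlation (adjusted p = 0.154). Tagln was at least 4.76-fold higher, Tpm2 rose by at least 2.69, and Acta2, which encodes smooth muscle actin, rose by 1.21. Extracellular matrix genes rose in 26 of 26 members, with a median of 2.35 (2.14 relative to all genes; camera adjusted p = 1.77e-06, and adjusted p = 0.0137 with an estimated correlation). Timp1, an inhibitor of matrix metalloproteinases, rose by at least 4.74 (adjusted p = 1.21e-10), Col6a2 was at least 4.72-fold higher, and Dcn, Col1a2 and Col3a1 rose by 3.74, 3.40 and 3.30. Endothelial genes rose in 12 of 15 members and fell in 2, and the list did not pass (median 1.15, 0.95 relative to all genes, 0.87 with dim members at their bounds; camera adjusted p = 0.0514). Kdr, a receptor for vascular endothelial growth factor, was at least 2.57-fold higher and Sox18 at least 1.56-fold higher, and the means of Icam2 lay below the array median in both groups, which gives no size of change, and its probe sets went in both directions. The list passed when control replicate 1, 2, 5, 7, 8, 9 or 10 was left out, with adjusted p-values between 0.0423 and 0.0491. With arrays centred on the Sertoli cell list the endothelial median turned to -0.58.

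Macrophage genes rose in 19 of 24 members and fell in 3, with a median of 2.24 (2.04 relative to all genes, 1.79 with dim members at their bounds; camera adjusted p = 0.00647). With an estimated correlation the list did not pass (adjusted p = 0.165). C1qa, a chain of the complement starter C1q, rose by at least 3.20 (adjusted p = 2.29e-08), Ptprc, the pan-leukocyte marker CD45, was at least 2.79-fold higher, and Cd163, a scavenger receptor of resident macrophages, was at least 5.75-fold higher. Aif1 fell by 3.25 (0.56 in another probe set) and Adgre1 was at least 1.69-fold lower. Lymphocyte genes showed 3 higher and 3 lower members of 8 and no list shift (camera adjusted p = 0.789). Their median was 0.12 (-0.08 relative to all genes) and their mean -0.01. The median turned to -0.09 after quantile normalization, where that of all genes was -0.06. Cd8b was at least 1.10-fold and Ms4a1 at least 1.26-fold lower. Of 4 tested mast cell genes 1 rose and 2 fell, Cpa3 by 0.50 or more and Tpsb2 by 0.94 ± 0.32 (camera adjusted p = 0.726 for the list). Without irradiated replicate 3 the Tpsb2 log2 change was -0.49 (adjusted p = 0.0244), and with control replicates 1 to 5 or 6 to 10 only it did not pass (adjusted p = 0.0674 and 0.0682).

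Genes of interferon response and MHC class I rose in 18 of 21 members, fell in 1, and had a median of 2.42 (2.21 relative to all genes, 1.38 with the 6 dim members at their bounds; camera adjusted p = 0.000394). This call did not hold with an estimated correlation (adjusted p = 0.0772). The guanylate binding protein gene Gbp2 was at least 10.4-fold higher, the immunoproteasome subunit Psmb9 rose by at least 3.69, and B2m, the light chain of MHC class I, rose by 3.61, whereas Ifit1 fell by 0.78. Complement genes rose in 6 of 7 members, with a median of 3.55 (3.35 relative to all genes; camera adjusted p = 0.0388). With an estimated correlation the adjusted p was 0.222, and with a filter at the 75th percentile it was 0.0564. Serping1, the inhibitor of C1, rose by 4.55 ± 0.08 (adjusted p = 3.49e-17) and C1s by 4.42, and Cd55, which protects cell surfaces from complement, was at least 7.47-fold lower. Of 26 inflammation and chemokine genes, all on the array, 14 passed the filter and were tested. Of these 10 rose and 1 fell. Their median was 1.48 (1.28 relative to all genes, 1.20 with dim members at their bounds, camera adjusted p = 0.0223). It turned to -0.25 with arrays centred on the Sertoli cell list. The adjusted p was 0.0663 with an estimated correlation. The tumour necrosis factor receptor gene Tnfrsf1a was at least 14.8-fold higher and the chemokine gene Cxcl12 rose by 3.91 ± 0.13.

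Targets of p53, the transcription factor activated by DNA damage, rose in 12 of 15 members and fell in 3, and the list did not pass (median 1.20, 0.99 relative to all genes; camera adjusted p = 0.0853). Its median turned to -0.53 with arrays centred on the Sertoli cell list. Cdkn1a (1388674_at), an inhibitor of the cell cycle, rose from 0.49 ± 0.16 (SD, n = 10) to 1.69 ± 0.12 (SD, n = 5), a change of 1.20 ± 0.09 (SE, adjusted p = 2.82e-09). After centring on the Sertoli cell list, its change was -0.53. Gadd45a rose by at least 2.69 and Ccng1 by 2.67. Polk, a DNA polymerase, was at least 1.88-fold lower, and Mdm2, which encodes the ubiquitin ligase of p53, fell by 4.01 ± 0.13, although its probe sets went in both directions, from -4.01 to 0.28. Cell cycle genes fell in 21 of 26 members and rose in 3, with a median of -2.43 (-2.63 relative to all genes, -2.10 with dim members at their bounds; camera adjusted p = 8.05e-06, and adjusted p = 0.0488 with an estimated correlation). Prc1 fell by 4.17 ± 0.14, the mitotic checkpoint kinase Bub1b was at least 2.46-fold lower, and Top2a changed by at most -2.86, whereas Ccnd1, which encodes cyclin D1, rose by at least 2.32.

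Niche growth factor and hormone receptor genes rose in 11 of 19 members and fell in 5, and the list did not pass (median 1.88, 1.67 relative to all genes; camera adjusted p = 0.0853). The Notch ligand Jag1 was at least 3.33-fold higher, and Igf1 and Pdgfra rose by 3.74 and 3.62. Kitlg, Dhh, Lhcgr and Cxcl12 in this list also belong to lists above. Antioxidant and glutathione genes rose in 16 of 20 members and fell in 3, with a median of 1.46 (1.26 relative to all genes; camera adjusted p = 0.00704) that turned to -0.27 with arrays centred on the Sertoli cell list. The adjusted p was 0.222 with an estimated correlation. Gstp1 rose by 3.67 ± 0.16 and Gpx1 by 3.56 ± 0.19, while Gpx4, the selenoprotein abundant in sperm, fell by 2.29, although another probe set rose by 1.09. Retinoid genes were split, with 4 of 12 higher and 6 lower (median -0.27, -0.47 relative to all genes, -0.07 with dim members at their bounds; camera adjusted p = 0.726), and fry's direction was opposite to the median. The retinal dehydrogenase Aldh1a1 rose by 3.21 ± 0.09 and its relative Aldh1a2 fell by 3.03, and Rdh11 fell by 3.11 ± 0.14. In the list of blood, adipose and epididymis genes (camera adjusted p = 0.726, median 0.51, 4 members), the globin gene Hbb rose by 2.24 ± 0.25 and Slc4a1 of the red cell membrane was at least 1.26-fold lower. Hbb did not pass with arrays centred on the Sertoli cell list (adjusted p = 0.0522), nor Slc4a1 with control replicates 1 to 5 only (adjusted p = 0.0783).

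**Figure D3:**
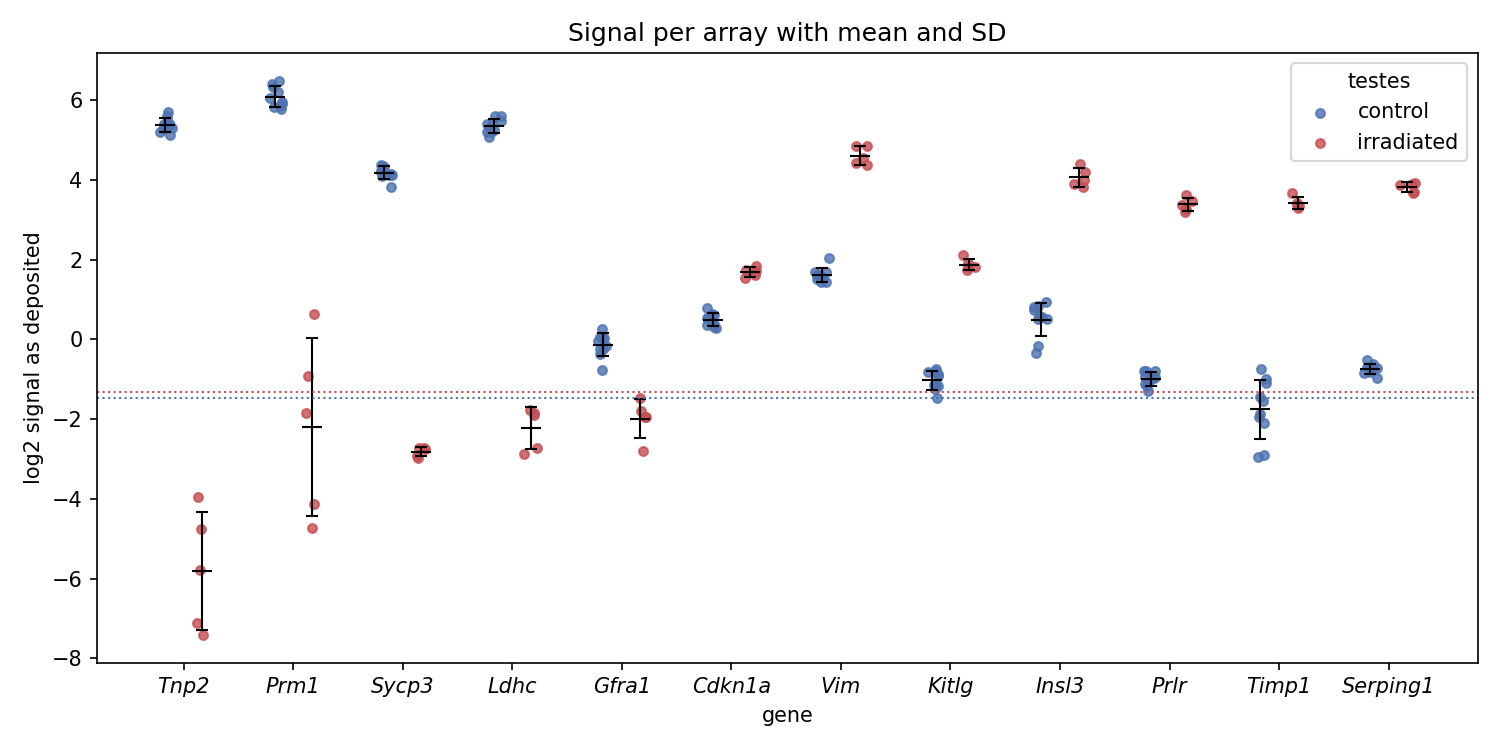
Log2 signal as deposited of 12 genes, 1 point per array (blue, 10 control; red, 5 irradiated), with the mean and SD in black. Dotted lines are the mean array medians of control (-1.47) and irradiated arrays (-1.31), below which a signal gives no order; Prm1 spreads most among irradiated arrays (SD 2.24), and the points of both groups do not overlap in any of these genes.

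List medians in each array were also set against the median of all genes. This difference rose by 1.49 for Sertoli cell genes and, among lists that did not pass with camera, by 1.03 for endothelial genes, 0.89 for p53 targets, 0.86 for cholesterol synthesis and 1.68 for niche growth factor and hormone receptor genes, and fell by 0.75 for retinoid and 0.54 for mast cell genes, with the groups apart in each (exact permutation, adjusted p = 0.0004 for each over 24 lists). Inflammation genes rose by 0.90 (adjusted p = 0.0004), and lymphocyte (0.09, adjusted p = 0.404) and blood, adipose and epididymis genes (0.15, adjusted p = 0.291) did not pass. This test takes the 15 arrays as units and camera the genes. Each adjusted p of 0.0004 comes from the smallest p this exact permutation test can give, 0.000333. Since the groups also lay apart in 69.5% of all genes tested, passing it does not set a list apart from other genes.

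Since the germ cell lists fell in the same arrays, the other lists were also set against the Sertoli cell list within each array, as the difference between list medians. A list that moved like all genes falls by 1.49 on this measure. The difference rose after irradiation by 1.36 for Leydig cell genes, by 2.49 for complement genes and by 0.44 for extracellular matrix genes (exact permutation, adjusted p = 0.000511, 0.000511 and 0.00239 over 23 lists). It fell by 0.46 for endothelial genes (adjusted p = 0.018), by 0.61 for p53 targets, by 0.59 for inflammation genes and by 0.63 for cholesterol synthesis genes (adjusted p = 0.000511 for each, exact permutation). The differences for peritubular myoid (0.13, adjusted p = 0.269), macrophage (0.17, adjusted p = 0.226), interferon (-0.09, adjusted p = 0.448) and antioxidant genes (0.17, adjusted p = 0.129) did not pass the exact permutation test. Neither did those for niche growth factor and hormone receptor genes (0.18, adjusted p = 0.1665) and Sertoli junction genes (0.05, adjusted p = 0.488). For undifferentiated and differentiating spermatogonia it fell by 1.73 and 1.08, and for lymphocyte, mast cell, retinoid and blood, adipose and epididymis genes by 1.40, 2.03, 2.24 and 1.35 (adjusted p = 0.000511 for each, exact permutation). Centring arrays on the Sertoli cell list and taking the median of member changes gave other values for some lists. They were 0.69 for interferon, 0.50 for Sertoli junction, 1.82 for complement and -0.27 for antioxidant genes. For interferon and antioxidant genes the sign relative to the Sertoli cell list thus depended on the measure.

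Of the 24 lists, 14 passed with camera's preset correlation, 10 higher and 4 lower, 6 passed with an estimated correlation and 22 with fry, which tests whether a list's genes move 1 way on balance and does not compare them with other genes. Members past the threshold adjusted over the list alone were as many as over all genes tested in each list except differentiating spermatogonia, where 4 passed in place of 3.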

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

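The test with the actin ratio as a covariate was chosen after the actin values had been seen, and the others in this part before their results. Values of named genes, list means and quality measures were searched within each group for an array far from the others (Dixon's test, 95% level). Of 194 sets of values, 13 held such an array, where chance gives about 1 in 20. Among control arrays, replicate 6 had the highest Vim signal (2.04, others 1.43 to 1.70), the lowest Rdh11 signal (1.66, others 1.99 to 2.29) and the lowest macrophage list mean (-1.37, others -1.09 to -0.85). Control replicate 2 had the lowest Slc4a1 signal (-2.95, others -1.34 to -0.27), replicate 9 the lowest Sycp3 (3.83, others 4.10 to 4.38) and Serpinb9 signals (-4.43, others -2.84 to -1.04), and replicate 4 the highest round spermatid list mean (2.92, others 2.61 to 2.75). Among irradiated arrays, replicate 1 had the highest signals of Testin (3.31, others 2.76 to 2.90), Timp1 (3.68, others 3.31 to 3.41) and Fabp9 (-4.14, others -7.17 to -6.67) and the lowest of Hspb9 (-3.18, others -1.53 to -0.99). Irradiated replicate 2 had the lowest Ms4a1 signal (-3.36, others -2.06 to -1.67), and replicate 4 the highest Leydig cell list mean (2.64, others 2.30 to 2.37). Several of these values lie below the array median.

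The signals of the rat Gapdh control probe sets were higher in every irradiated than in every control array. The mean difference was 1.80 for the 3' probe set, 1.81 for the 5' probe set and 1.25 for the middle one. The lowest irradiated values were 3.89, 3.52 and 3.20 and the highest control values 2.55, 2.47 and 2.65.

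The lists of 5 somatic cell types had higher medians in irradiated testes, at 2.74 for Leydig cells, 2.24 for macrophages, 1.84 for Sertoli cells, 1.76 for myoid cells and 1.15 for endothelium. Loss of germ cells alone would raise all alike only if their signals came from somatic cells and lay above the array median. The medians spanned 1.59 log2 units. Moving members between the 5 lists at random gave a range as large with a permutation p of 0.0324. This does not decide on a rise in share alone. Of the members, 7 of 15 endothelial and 6 of 24 macrophage genes were dim in a group, and the permutation takes genes as independent. The smallest of the 5 medians was still 0.814 under quantile normalization and median centring. Both set the arrays of the 2 groups to a shared level, so they do not decide whether scaling sets the direction. For the endothelial list the direction turned with centring on the Sertoli cell list. Part of these rises may still come from a larger share of somatic RNA: with centring on the Sertoli cell list, which shifts all genes of an array alike, the medians were 1.01 for Leydig cells, 0.51 for macrophages, 0.03 for myoid cells and -0.58 for endothelium. Open and untested are changes in cell numbers per Sertoli cell, in RNA per cell and in time since irradiation. No group difference in 3' bias was seen in the actin and Gapdh probe sets. Their 3' minus 5' differences changed by 0.008 and -0.007 log2 units (exact permutation p = 0.967 and 0.974). The SDs among control arrays were 0.42 and 0.45, so a modest difference between the groups could be missed. As a covariate the actin ratio moved no list (smallest median 1.15), which says little, since it hardly differed between the groups. Other aspects of RNA quality remain open.

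Chance in the assignment of arrays was examined with 100 splits of the 15 arrays into 10 and 5, the real one included. For probe sets, 1 of the 100 splits, the real one, gave as many past the threshold (15598, highest other 12149). For genes it was also 1 of the 100 (9272, highest other 7404). A chance assignment of the arrays is thus argued against for both counts, within the 100 of 3003 splits drawn. The splits cannot speak on a batch difference that goes with the groups. For gene lists, 21 of the 100 splits gave at least 14 lists past the threshold, with 15 as the highest other. The number of lists alone does not decide on chance, for the reason given next. None of the 35 splits that put 2 irradiated arrays in the group of 5 gave as many lists (highest 10), while 8 of 11 with 0, 4 of 39 with 1, 6 of 11 with 3 and 2 of 3 with 4 did. Splits with many lists thus mostly held an uneven share of irradiated arrays, a structure of these samples. Such splits still carry part of the difference between irradiated and control arrays, so their list counts do not measure chance alone. Apart from splits with 4 irradiated arrays, the drawn splits gave 0 genes past the limma threshold.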

How the results depend on the processing

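A pseudocount at the 10th percentile, leaving out the 3 controls with the highest actin ratio and the actin covariate were chosen after seeing the data. The counts of changed genes lay between 6534 (75th percentile filter, which tested fewer genes) and 10697 (no filter, which tested more), within 1.5 times 9272 under every alternative, and between 9070 and 9288 with 1 array left out. Without 1 array, higher genes numbered 5021 to 5170, lower genes 4015 to 4126, probe sets 15217 to 15649 (8916 to 9189 higher, 6214 to 6468 lower) and lists 14 to 15. Under the 75th percentile filter, 9442 probe sets passed, 5360 higher and 4082 lower, since fewer were tested. Centring on the Sertoli cell list gave 2439 higher and 13755 lower probe sets and 1360 higher and 8199 lower genes, because it shifts all genes by the same amount in an array; 2528 genes past the threshold both ways changed direction, and Cdkn1a turned to -0.53. With an estimated correlation 6 lists passed and with fry 22. Without a filter, which adds members, medians relative to all genes changed sign in 3 lists. Differentiating spermatogonia turned from 0.49 to -0.15, lymphocytes from -0.08 to 0.10 and blood, adipose and epididymis genes from 0.30 to -0.48. Lymphocytes turned to 0.0661 with control replicates 1 to 5, alone or with the replicate block; the cause was not tested. None of these 3 lists passed with camera.

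Of calls on single lists and genes, complement was lost under the 75th percentile filter (adjusted p = 0.0564), Hbb under Sertoli centring (0.0522), Tpsb2 with control replicates 1 to 5 (0.0674) or 6 to 10 (0.0682) and Slc4a1 with control replicates 1 to 5 (0.0783). The endothelium list (0.0514) ranged from 3.9e-11 with fry to 0.165 with an estimated correlation and passed without a filter, under the pseudocounts and scalings and with the mean of a gene's probe sets. Cholesterol synthesis, p53 targets and niche factors passed under some of these alternatives and with fry, and 8 lists that passed did not with an estimated correlation. The alternatives keep each gene's representative probe set, a choice made after a first run in which they were chosen anew and complement was lost under the block. Low signals limit the size of the largest changes: without detection calls, 1311 of the lower genes have only a bound.

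Samples of the groups share numbers 1 to 5 in the labels, and nothing else pairs them. Correlations of same-numbered arrays' deviations from their group means were -0.0473, 0.0366, 0.0151, -0.0377 and 0.0692, and only irradiated replicate 5 correlated best with its own number. With the replicate block on these 10 arrays, 8950 genes passed (5000 higher, 3950 lower), 15123 probe sets and 15 lists; the endothelium list passed (0.0364) and Tpsb2 did not (0.0843). No other call on a list or named gene changed.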

Other observations

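The test against autosomal housekeeping genes was chosen after the result of the X-linked list had been seen, and the other tests before theirs. Widely expressed genes of the X chromosome, a list of 80 written from textbook knowledge, rose in 59 of 64 tested members, fell in 3 and did not pass in 2. Their median change was 1.93 (quartiles 1.36 and 2.89). Sat1, which encodes a polyamine acetyltransferase, rose by 3.97 ± 0.12 (SE), the filamin gene Flna by 3.08 ± 0.13 and the cohesin subunit gene Stag2 by 3.03 ± 0.08. The ubiquitin-conjugating enzyme Ube2a, whose product acts in DNA repair, fell by 1.30 ± 0.13 and the mitochondrial enzyme Hccs by 0.95 ± 0.16, although another probe set of each rose, by 1.05 and 2.03. These genes were chosen after their values were seen.

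Several enzymes and proteins have a form made by germ cells and another made by most cells. Of 24 such pairs, 12 had both forms tested. The germ cell form fell in 11 of 12, and the somatic form rose in 9 and fell in 2. Of the somatic forms that rose, Pdha1, Cstf2 and Smc1a also belong to the X-linked list. The ADP/ATP carrier gene Slc25a4 rose by 3.03 ± 0.10 while its germ cell form Slc25a31 was at least 3.54-fold lower, and Cox6b1 rose by 2.08 ± 0.10 while Cox6b2 was at least 37.7-fold lower. The calcineurin subunit Ppp3ca rose by 2.90 ± 0.15 and Ppp3cc changed by at most -1.83. Ldha was an exception, falling by 1.55 ± 0.13 together with its germ cell form Ldhc (at least 101-fold lower), and Cstf2t, a germ cell form, rose by 0.59 ± 0.09.

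A candidate explanation for the X-linked genes is that meiotic and later germ cells silence the X chromosome, so that X-linked RNA gains share when these cells are lost. The list's median lay at the 100th percentile of 10000 random lists matched on mean expression, whose own median was 0.26. Wide use of housekeeping genes in somatic cells, whatever their chromosome, is argued against: a list of 75 tested autosomal housekeeping genes had a median of 0.51, lower by 1.43, with a permutation p of 1e-05, the smallest these permutations can give. The difference was 1.28 after quantile normalization, and centring on the Sertoli cell list lowered the X-linked median itself to 0.20. Both lists were put together by hand, and a different mix of gene functions in them remains open.

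For the pairs, the hypothesis that germ cells use the testis-specific form and somatic cells the other predicts a fall of the first and a rise of the second, which was seen in 8 of 12 pairs. The number was also 8 after quantile normalization and median centring and 5 after centring on the Sertoli cell list. These counts do not decide on the hypothesis. The pairs were chosen for having a germ cell form, so its fall was largely set once the germ cell lists fell. Somatic forms rose in 9 of 12 pairs and autosomal housekeeping genes in 42 of 75, and these shares were not compared by a test. In all 12 pairs the somatic form changed upward relative to the germ cell form in the deposited values and after quantile normalization. This may reflect a change in cell makeup, and changes of expression within a cell type were not tested.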
